A study of Mus musculus with 10 samples.

How the data were processed

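Total RNA was extracted from mouse heart with a column kit and DNase treatment, per the labels' protocols, and sequenced on an Illumina instrument. HISAT2 and HTSeq with the mouse build mm10 are named per the submitters' processing notes, without versions. For each model the authors deposited a table with a score per gene and sample, which are per-million values rounded to whole numbers. Whether they are TPM or CPM, and how they were scaled, adjusted and rounded, is not given in the sources used here. The samples sum to between 998498 and 1001508, so depth is lost and no counting interval can be given. A value of 1 is the largest in 2915 genes at E15.5 and 2457 in the adult. The tables also hold the authors' own log2 fold changes and p-values, under column names as DESeq2 writes them, per the file headers. Their mean column was recomputed from the rounded values to within 3.1e-09 (relative), so the authors' statistics were computed on these per-million values. The sign of their test statistic is opposite to that of the authors' log2 fold change in all 15498 and 15989 genes. An adjusted p-value is given in the deposited table for 2601 genes at E15.5, each with a mean of at least 83.4.

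The control and knockout values of the same replicate number add to the same total, within 2, in 8328 of 8366 E15.5 genes with a mean of at least 10 and in 8642 of 8658 adult genes. Other pairings of the numbers gave this for 4.98% to 19.44% and for 28.56%. Of the genes outside this tolerance, at any mean, 180 of 181 at E15.5 and 27 of 27 in the adult met the total once a single value was given a negative sign. Deviations of same-numbered samples from their group means are therefore mirror images (correlation across genes, which are not independent replicates, between -0.82 and -0.80 at E15.5, and -0.81 in the adult), and this holds by construction, not as a pairing stated in the labels. Each gene thus has 2 independent residual degrees of freedom at E15.5 and 1 in the adult.

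Knockout was compared with control within each table by limma 3.58.1 in R 4.3.3, on log2(value + 1). Genes that reached a value of 1 in fewer samples than a group holds were left out, and p-values were adjusted by Benjamini-Hochberg at 0.05. The reported fit has the replicate number as a block, adds the variance of rounding (0.0833 on the scale of the values) to each gene's variance, and uses eBayes with trend and robust options. This draws a gene's variance toward that of genes of similar level. The median prior had 27.54 degrees of freedom at E15.5 and infinite ones in the adult. The SE and p-value of the median adult gene thus rest on spread pooled over genes, not on its own. A fit with no replicate block treats mirrored deviations as independent; the block raised the standard errors by a median factor of 1.605 at E15.5 and 1.834 in the adult, and the planned fit without it called 701 higher and 339 lower genes at E15.5. The groups, the gene lists, the rule for named genes, the threshold and most of the other settings were chosen before the data were examined. The fit planned then had neither the block nor the rounding variance. It was replaced after the values had been examined and after 36 combinations of filter, block, rounding variance and prior had been run on each table, so the choice was made with call counts known. The ground for it is the fixed totals and the rounding.

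The fits were tested on simulated data with fixed totals and rounding, in 5 simulations with 100 genes changed by a factor of 2 and 100 by a factor of 1.5, and with noise settings picked among several so that the spread resembled the deposited values. At E15.5 the reported fit recovered a mean of 24.4 of the 2-fold and 1.6 of the 1.5-fold genes, and of its mean of 29 calls 10.3% were false. The planned fit recovered 60 and 42 with 86.6% false, and rounding variance without the block 63.4 and 35 with 37.5% false. In the adult the reported fit recovered 95.6 and 69 with 53.5% false, the planned fit 42.8 and 37.8 with 95% false, and rounding variance without the block 66.6 and 49.4 with 38.9% false. No fit that made calls in the adult held false calls near the nominal share. These shares hold for the number of changed genes set in the simulations, which is unknown for the deposited values.

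Gene lists, 36 in number of which 35 could be tested in each model, were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Some genes stand in several lists. Camera sets a list against the other tested genes, so its direction can differ from the sign of the list's median. Over all tested genes the median log2 change was 0.107 at E15.5 and 0.076 in the adult. With median-of-ratios scaling it was 0.044 and 0.017. Larp7 was left out of the lists. The named genes are Larp7, up to 10 of the largest rises and of the largest falls per model among called genes with a mean of at least 8 and no overlap between groups (leaving out unnamed and sex-linked genes), up to 3 called members of each list or else its 2 most abundant, up to 10 genes called in both models, and 15 genes fixed in advance. Gene names are printed as the tables give them, with a point for a hyphen. Coordinates are from GENCODE M21. Genes with near-identical copies, such as the globins, and antisense partners are uncertain, since strand use in counting is not given in the sources used here. Count-based tests, library-size normalization for counts, a sex covariate and a test of the difference between the models were not run. Count-based tests need counts, and the test between the models was planned for counts only and the tables were normalized separately. The sex covariate was left out after the sex-linked genes were looked at. Fixed totals per replicate number could hide a sex difference between numbers, and Xist was called as higher in the adult knockout, so these values cannot show whether sex varied.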

Results

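RNA from the hearts of mice lacking LARP7, an RNA-binding protein that holds the noncoding RNA 7SK in the complex restraining the elongation kinase P-TEFb, was compared with control heart RNA in an embryonic and an adult model on the C57BL/6 background. At embryonic day E15.5 there were 3 samples of whole wild-type hearts and 3 of Larp7 knockout hearts. At 4 months of age there were 2 samples of apex tissue from controls with floxed Larp7 alleles and 2 from mice in which Cre driven by the cardiomyocyte promoter of Myh6 deletes the gene. The sources used here do not say that samples of a group came from separate animals, so p-values measure only the spread between these samples. That spread is drawn in part from other genes of similar level, and in the adult wholly so for the median gene. The deposited tables list 15498 genes at E15.5 and 15989 in the adult, as per-million values rounded to whole numbers, and the values of a sample sum to between 998498 and 1001508, so that sequencing depth is unknown. Within nearly every gene the control and knockout values of the same replicate number add to a fixed total. As a result the SDs printed for both groups of a gene are nearly equal and are not independent estimates. Every fold change is on the log2(value + 1) scale and compares knockout with control.

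At E15.5 the question was what differs in the developing heart of the Larp7 knockout. Larp7, on the minus strand of chromosome 3 from 127536714 to 127553349 in mm10, fell from 95.7 ± 7.51 (SD, n = 3) in the wild type to 46.3 ± 7.09 (SD, n = 3) in the knockout, a log2 change of -1.04 (SE 0.17, adjusted p = 0.00159, limma with Benjamini-Hochberg adjustment). Its values were 96, 88 and 103 in the wild-type hearts and 45, 54 and 40 in the knockout hearts, without overlap. It lost its call, at the same log2 change, under 4 other settings (adjusted p between 0.332 and 0.473, limma). The authors' deposited table gives a log2 change of -1.11 for Larp7 with an unadjusted p of 1.84e-05. Signal from the gene thus remained in the knockout samples; which part of the gene was deleted is not given in the sources used here.

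Genes of mitochondrial oxidative phosphorylation were lower in the knockout hearts at E15.5. Of 24 complex I subunit genes 23 had a negative change, with a median of -0.52 (limma camera, adjusted p = 2.32e-24, or adjusted p = 7.63e-05 with an estimated correlation), and 3 were called singly. These were Ndufb7 (141.7 ± 17.0 against 84.3 ± 17.0, SD, n = 3), Ndufc1 (91.7 ± 8.74 against 54.3 ± 8.74) and Ndufa13 (132.7 ± 10.4 against 81.3 ± 10.4). Adjusted over the list alone, 18 complex I genes fell. Of 34 genes for complexes II to V, 33 had a negative change, with a median of -0.41 (camera, adjusted p = 4.18e-21, or adjusted p = 0.00388 with an estimated correlation). In limma 0 were called over all genes, and 14 fell when adjusted over the list alone. All 13 mitochondrially encoded genes had a negative change with a median of -0.89 (camera, adjusted p = 6.37e-11, or adjusted p = 0.0245 with an estimated correlation) and 4 lower when adjusted over the list alone. The single values varied widely there: mt.Cytb had 13517 ± 1638 in the wild type and 7378 ± 1638 in the knockout, whereas mt.Co1 had 22055 ± 8379 and 17045 ± 8379 (SD, n = 3). By fry the complex I, complex II to V and mitochondrially encoded lists were not called (adjusted p = 0.178, 0.182 and 0.289).

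The mitochondrial ribosome followed the same direction at E15.5, with 55 of 59 genes negative and a median of -0.29 (camera, adjusted p = 1.89e-23, or adjusted p = 0.000661 with an estimated correlation). Mrps26, a small-subunit protein, was the single called member, at 54.3 ± 3.79 against 32.3 ± 3.21 (SD, n = 3), and 17 members fell when adjusted over the list alone. The tricarboxylic acid cycle and pyruvate dehydrogenase genes were lower as a group (median -0.18, camera, adjusted p = 0.000619), with 12 of 16 negative, 0 called over all genes in limma, and 1 lower over the list alone. The 23 measured regulators of mitochondrial biogenesis did not shift as a group (median 0.07, camera, adjusted p = 0.953) with 0 called in limma over all genes or over the list alone. Tfam, which packages mitochondrial DNA, was 72.7 ± 3.06 in the wild type and 69.3 ± 3.06 in the knockout. Nrf1 was 51.3 ± 6.03 and 52.7 ± 6.51, Sirt1 was 29.7 ± 2.08 and 31.7 ± 1.53, and Ppara was 19 ± 1.73 and 19.7 ± 1.53. The coactivators Ppargc1a (186 ± 35.1 against 229.7 ± 35.2) and Ppargc1b (40 ± 12.8 against 66 ± 12.8) had higher knockout means that did not pass the test (adjusted p = 0.474 and 0.358, limma). Of the genes fixed in advance, Esrra, Myh6, Myh7, Cdkn1a and Atm are not among the genes listed at E15.5 and could not be tested there. Lists also had fewer tested members at E15.5 than in the adult: 24 against 36 for complex I, 19 against 25 for the sarcomere and 14 against 26 for p53 targets.

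Muscle genes went both ways in the embryonic hearts. The sarcomere list was lower (15 of 19 negative, median -0.30, camera, adjusted p = 1.28e-06, or adjusted p = 0.00514 with an estimated correlation), with Tnnc1, cardiac troponin C, falling from 1110 ± 86.3 to 654 ± 85.9 (log2 -0.77, SE 0.18, adjusted p = 0.0449, limma). Tnnc1 was the 1 member called, over all genes and adjusted over the list alone, and lost its call over all genes without number 1 of the knockout (adjusted p = 0.103, limma). Ckm, the muscle creatine kinase, fell from 769.7 ± 74.7 to 388.3 ± 74.7 (log2 -1, SE 0.18, adjusted p = 0.00875, limma), and Cav3, the muscle caveolin, from 118.3 ± 7.64 to 69.7 ± 7.64 (adjusted p = 0.0211, limma). Ckm stands in the skeletal muscle list, which was called as lower (camera, adjusted p = 0.0379) with 3 of 6 members negative, 1 called over all genes and 2 lower when adjusted over the list alone. That list lost its call when either number 1 or number 3 sample was left out, with no filter on low values (median 0.33, of opposite sign) and with a mean of at least 10 (median -1). Atrial and conduction markers were higher (11 of 11 positive, median 0.57, camera, adjusted p = 0.000107, or adjusted p = 0.00358 with an estimated correlation), with Nppa, the atrial natriuretic peptide, rising from 959 ± 86.9 to 1773 ± 86.3 (log2 0.89, SE 0.19, adjusted p = 0.0186, limma) and 4 members rising when adjusted over the list alone. Nppa lost its call without number 1 of the knockout (adjusted p = 0.236, limma). The median of the atrial list was 0.18 without number 3 of the wild type and 0.80 without number 2, and the list was called without any 1 sample. The wider list of fetal and stress genes was not called (camera, adjusted p = 0.952), with Nppa its 1 called member and 4 higher and 1 lower when adjusted over the list alone.

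The integrated stress response and mitochondrial unfolded protein response list was higher at E15.5, with 20 of 22 members positive and a median of 0.59 (camera, adjusted p = 1.67e-10, or adjusted p = 4.01e-05 with an estimated correlation). Its called members were Mthfd2, a mitochondrial folate enzyme (39.3 ± 6.35 against 73.7 ± 6.35), Sesn2 (12.3 ± 2.52 against 23.7 ± 2.52) and Chac1 (1.67 ± 1.15 against 8.33 ± 2.52, SD, n = 3), the last with a wild-type value that meets the fixed total only with a changed sign. Adjusted over the list alone 13 members rose and 1 fell. The p53 target list was called as higher (median 0.15, against 0.107 over all tested genes, camera, adjusted p = 0.0325, or adjusted p = 0.15 with an estimated correlation), with Sesn2, Btg2 (155 ± 25 against 262.7 ± 24.8) and Eda2r (6.67 ± 0.58 against 14.3 ± 0.58) rising, 4 members when adjusted over the list alone. Sesn2 also stands in the integrated stress response list and Btg2 in the immediate early list, so these lists are not independent. Matrix genes (adjusted p = 0.000972), hypoxia targets (adjusted p = 0.00801) and immediate early genes (adjusted p = 0.0267) were also called as higher by camera. With an estimated correlation these became adjusted p = 0.555, adjusted p = 0.555 and adjusted p = 0.372. Over all genes 0, 0 and 1 of their members were called in limma, and 3, 2 and 3 rose when adjusted over the list alone. The matrix, hypoxia, p53 and immediate early lists were not called when either number 3 sample was left out (lowest medians 0.21 for matrix, 0.19 for hypoxia and 0.19 for immediate early genes), nor were p53 targets and immediate early genes without either number 1 sample. Hypoxia and immediate early genes also lost their calls without rounding variance, with or without the replicate block, and immediate early genes without the genes that hold a value with a changed sign.

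Markers of other cell types had positive medians beside these lists and were not called by camera. They were 0.28 for endothelial (adjusted p = 0.39), 0.23 for fibroblast (8 of 10 positive, adjusted p = 0.159), 0.42 for epicardial (adjusted p = 0.464), 0.52 for erythroid (12 of 14 positive, adjusted p = 0.465), 0.28 for smooth muscle and pericyte (adjusted p = 0.283) and 0.14 for macrophage markers (adjusted p = 0.953). Over all tested genes the median was itself 0.107. For the smooth muscle and pericyte list and the macrophage list the direction of the camera test was lower, despite the positive medians. The smooth muscle and pericyte list was called as lower with no replicate block and no rounding variance. The medians of these marker lists moved with single replicate numbers: without number 3 of a group the lowest were -0.03 for erythroid, -0.16 for smooth muscle and pericyte, -0.11 for macrophage, 0.02 for epicardial and 0.04 for fibroblast markers. The endothelial median was 0.08 without number 2 of the knockout. With the replicate block, leaving out a sample also takes its same-numbered partner out of the comparison, so the dependence cannot be assigned to 1 sample of a pair. Epicardial and erythroid markers were called as higher without either number 1 sample, and fibroblast markers without either number 2 sample. Pdgfra, a fibroblast receptor, rose from 70.7 ± 1.53 to 116 ± 1.73 (SD, n = 3), and Rgs5 fell. Neither was called without number 1 of the knockout (adjusted p = 0.16 and 0.0867, limma).

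Among single genes at E15.5, 72 were higher and 14 lower in the knockout of 13609 tested (limma, adjusted p under 0.05). The largest rises included Tnfrsf9 (log2 1.91, SE 0.25), Hs3st3b1, a heparan sulfate sulfotransferase (log2 1.66, SE 0.21), and Clic6 (log2 1.59, SE 0.25). Each of these stood at 13.3 or less in the wild type. The falls included Ramp1 (71.3 ± 5.51 against 35.7 ± 5.51, SD, n = 3), Rgs5, a pericyte marker (79.7 ± 3.51 against 42.7 ± 4.04), Gbas (1483 ± 156 against 859.3 ± 156) and Cops5 (113 ± 4.36 against 68.7 ± 4.73). Genes of stratified epithelium, looked at after their values were seen and not tested as a list, stood apart in number 1 of the knockout: Krt15 was 74 there against 19 and 19 in the others, Sfn 69 against 19 and 18, Cldn4 32 against 8 and 8, and Krt10 26 against 8 and 9. In each of these genes the value of number 1 of the wild type meets the fixed total only with a changed sign. Krt15 was 36 in that sample against 18 and 18 in the other wild-type samples. Without number 1 of the knockout Lad1, an anchoring filament protein of epithelia, had a log2 change of 1.23 and was not called (adjusted p = 0.0843, limma). Other genes named above lost their calls as well, among them Gbas (adjusted p = 0.471, limma), Nppa (0.236), Btg2 (0.195), Pdgfra (0.16) and Tnnc1 (0.103). Ckm (0.0253), Ndufb7 (0.0171) and Mthfd2 (0.0136) were among those that kept theirs. In all, 38 of the 86 calls held without number 1 of the knockout and 40 without number 1 of the wild type. Without number 2 of the wild type or knockout 78 and 73 held, and without number 3 it was 61 and 55. The calls of single genes rest on the test: with the replicate block and no rounding variance 0 genes were called (limma, 1422 at an unadjusted p under 0.05), and 0 when genes with a mean under 10 were left out (1100 at an unadjusted p under 0.05). Median-of-ratios scaling called 26 higher and 13 lower, 66.7% higher against 83.7%. Leaving out any 1 sample called 171 to 422 higher and 40 to 87 lower genes. The authors' deposited table gives 12 higher and 14 lower genes at an adjusted p under 0.05.

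**Figure D1:**
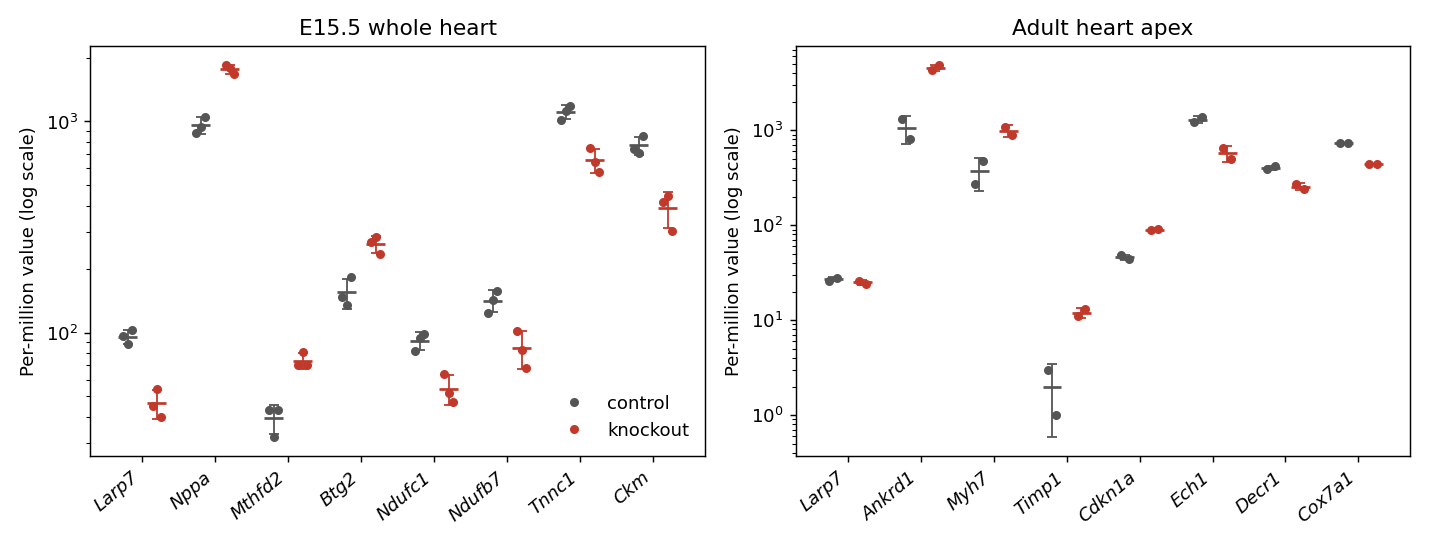
Per-million values of named genes in each sample, on a log axis, for E15.5 whole hearts (left, 3 samples per group) and adult apex tissue (right, 2 per group). Points are samples, horizontal lines are group means and bars are SDs; Larp7 is separated between the groups at E15.5 and overlaps in the adult.

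In the adult the question was what differs at 4 months when Larp7 is deleted through Myh6-Cre. Larp7 was 26 and 28 in the control apex and 26 and 24 in the knockout apex, a log2 change of -0.11 (SE 0.17, adjusted p = 0.933, limma), so that its RNA does not check the genotype labels here. The authors' deposited table gives a log2 change of -0.17 with an unadjusted p of 0.756. The share of apex RNA that comes from cells outside the Cre line was not measured.

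Genes of cardiomyocyte stress were higher in the adult knockout samples. All 20 members of the fetal and stress list had a positive change, with a median of 0.92 (camera, adjusted p = 2.14e-27), and 9 were called (11 adjusted over the list alone). The list was not called without rounding variance, with or without the replicate block (camera, adjusted p = 0.829 with the block). Nor was it called by fry (adjusted p = 0.121). Ankrd1, a stretch-responsive titin-binding protein, rose from 1054 ± 342 to 4563 ± 341 (SD, n = 2, log2 2.15, SE 0.13, adjusted p = 6.65e-52, limma). It was not called without rounding variance (adjusted p = 0.108 with no replicate block and 0.49 with the replicate block, limma), with rounding variance and no block (0.0504) or with the most cautious prior (0.109). Myh7, the slow myosin heavy chain, rose from 369 ± 140 to 991 ± 140 (log2 1.47, SE 0.14), and Gdf15 from 2.50 ± 2.12 to 15 ± 1.41. The SEs of Ankrd1 and Myh7 are largely pooled over genes of similar level and do not measure these genes' own spread. Nppa had 321 and 100 in the controls against 1189 and 1409 in the knockout, and Nppb 508 and 62 against 830 and 1274, so that their higher means did not pass the test over the spread between numbers (adjusted p = 0.716 and 0.877, limma). Nppa passed with the 75th percentile prior (adjusted p = 0.00566, limma) and without either control sample, and Nppb did not with that prior (0.0753). Myh6, the main adult myosin, was 19274 ± 72.8 and 16957 ± 72.1 and was not called. The sarcomere list did not shift (median 0.03, adjusted p = 0.369).

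Extracellular matrix genes were higher as a group in the adult knockout: 37 of 37 had a positive change, the median was 0.95 (camera, adjusted p = 7.06e-32), and 16 were called, 23 when adjusted over the list alone. With the estimated correlation of 0.52 in place of the preset 0.01 the list had an adjusted p of 0.00874 (camera). It was not called without rounding variance, with or without the replicate block (camera, adjusted p = 0.359 with the block), nor by fry (adjusted p = 0.152). The called genes included Timp1, a metalloproteinase inhibitor (2 ± 1.41 against 12 ± 1.41, SD, n = 2), Col8a1 (26.5 ± 9.19 against 62 ± 9.90) and Ccn2, connective tissue growth factor (87 ± 1.41 against 175.5 ± 2.12). The matrix median was 0.56 without number 1 of the controls and 1.33 without number 2. Fibroblast markers were higher with them (12 of 14 positive, median 0.40, camera, adjusted p = 1.43e-07, or adjusted p = 0.0261 with an estimated correlation, 3 called, and 6 higher and 1 lower over the list alone). Lum, Dcn, Col1a1, Col1a2 and Col3a1 stand in both the matrix and the fibroblast list, so these are not separate results. The called members included Mfap5 (34 ± 2.83 against 83 ± 2.83) and Mfap4 (28 ± 5.66 against 65.5 ± 6.36). Macrophage markers were higher (median 0.23, camera, adjusted p = 0.0127), with Fcgr1 called and 2 members rising over the list alone, and were not called without the number 2 sample of either group. Endothelial markers (median -0.04, adjusted p = 0.151) and smooth muscle and pericyte markers (median -0.10, adjusted p = 0.116) were not called. Epicardial markers had a median of 1.53 (camera, adjusted p = 2.56e-06, or adjusted p = 0.091 with an estimated correlation), with 6 rising over the list alone. The called members Krt19, Lrrn4 and Aldh1a2 stood at 11 or less in the controls, and the list was not called without number 2 of the knockout. Its median was 0.49 without number 2 of the controls and 2.11 without number 1.

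Fatty acid oxidation genes were lower as a group in the adult knockout. Of 32 members 27 had a negative change, the median was -0.40 (camera, adjusted p = 7.87e-21), and 13 fell (18 adjusted over the list alone, where 2 rose). Etfb, of the electron transfer flavoprotein, was 101 ± 21.2 against 53.5 ± 20.5, Decr1 401.5 ± 20.5 against 254.5 ± 20.5, and Acaa2 650.5 ± 21.9 against 428 ± 22.6 (SD, n = 2). Ech1, a peroxisomal and mitochondrial enoyl-CoA isomerase outside the list, fell from 1291 ± 113 to 572.5 ± 112. Complex I genes (35 of 36 negative, median -0.17, camera, adjusted p = 1.02e-10) and complex II to V genes (38 of 44 negative, median -0.18, adjusted p = 1.99e-10) were lower by small amounts, with Ndufs5 called among the former and Cox7a1 falling and Atpif1 rising among the latter, the same counts as over the lists alone. With an estimated correlation these 2 lists had adjusted p = 0.00503 and 0.0319 (camera). The tricarboxylic acid cycle list was lower (median -0.22, camera, adjusted p = 6.72e-09, or adjusted p = 0.0469 with an estimated correlation) with 0 members called in limma over all genes or over the list alone. The mitochondrial ribosome list was called as lower with a median of -0.02 (camera, adjusted p = 0.00728) and 31 of 74 members positive. Camera sets it against the other genes, and the median over all tested adult genes was 0.076. Mitochondrially encoded genes were not called (median 0.05, adjusted p = 0.39). Of the biogenesis regulators, Perm1 fell from 354 ± 22.6 to 258 ± 22.6 (adjusted p = 0.046, limma), and the list was not called (median -0.02, adjusted p = 0.0755), although it was called as lower with an estimated correlation (adjusted p = 0.0495) and with median-of-ratios scaling (median -0.08). Ppargc1a was 109 ± 1.41 and 91 ± 1.41 (adjusted p = 0.494, limma), Esrra 158.5 ± 13.4 and 147 ± 14.1, Tfam 41 ± 1.41 and 42.5 ± 0.71, Nrf1 12.5 ± 0.71 and 11 ± 0.00, and Ppargc1b 20 ± 2.83 and 23 ± 4.24, none called. The antioxidant list was not called (adjusted p = 0.53), although Gpx3, Srxn1 and Gclm rose (5 members over the list alone).

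Targets of p53 were higher in the adult (22 of 26 positive, median 0.35, camera, adjusted p = 4.71e-07), with 5 called and 7 rising over the list alone. Cdkn1a, the cell cycle inhibitor p21, was 46 ± 2.83 against 90 ± 2.83 (log2 0.95, SE 0.15), and Phlda3 13.5 ± 4.95 against 38 ± 4.24 (SD, n = 2). The DNA damage response list was not called (adjusted p = 0.8), and Atm was 6 ± 0.00 and 6.50 ± 0.71. Interferon response genes (median 0.71, camera, adjusted p = 8.42e-10, or adjusted p = 0.0501 with an estimated correlation) had 7 higher and 1 lower call, 15 and 1 over the list alone, with Ifi44 at 9 ± 5.66 against 23.5 ± 6.36. Their median was 0.35 without number 1 of the controls and 1.21 without number 2. Cell cycle genes (median 0.50, camera, adjusted p = 2.91e-07, or adjusted p = 0.15 with an estimated correlation) had 4 higher calls, 9 over the list alone, among them Ccnd2 (122 ± 22.6 against 231.5 ± 23.3). Calcium handling and ion channel genes were lower (median -0.15, camera, adjusted p = 1.23e-05, or adjusted p = 0.0679 with an estimated correlation) with 5 called, also over the list alone, among them the potassium channels Kcnd2 and Kcnj3. The integrated stress response list was at the threshold (adjusted p = 0.0493, or adjusted p = 0.092 with an estimated correlation), with Gdf15 and Mthfd2 called and 3 rising over the list alone, and it was called in 4 of 16 alternative settings. The 7SK and P-TEFb list was not called in either model, but Hexim1, the P-TEFb inhibitor held by 7SK, rose in the adult from 32 ± 5.66 to 48.5 ± 6.36 (log2 0.59, SE 0.16, adjusted p = 0.00931, limma). At E15.5 it was 35.7 ± 10.2 against 59 ± 10.6 (adjusted p = 0.239, limma). Cdk9 was 20 ± 0.00 in both adult groups.

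In all, 347 genes were higher and 141 lower in the adult knockout of 14835 tested (limma, adjusted p under 0.05). Further large falls were Strit1 (with a knockout value that meets the fixed total only with a changed sign), Ano10, Fbp2 and Slf1, and further large rises Kif26b, Serpina3n and Pygl. With 2 samples per group and 1 independent residual degree of freedom these calls are loose: on simulated values with fixed totals and rounding 53.5% of the genes called in the adult were false. That share depends on the number of changed genes, which was set in the simulation and is unknown here. The changed genes there all had a mean of at least 10, so it does not cover lower genes. A more cautious prior on the variances called 0 adult genes (limma model, 1724 at an unadjusted p under 0.05), and median-of-ratios scaling moved the share of higher calls from 71.1% to 57.6%. Of the 15 lists called in the adult, 0 were called by the fit without a replicate block or rounding variance (limma camera), whose 1 called list was adipocyte markers, and 2, complex I and fatty acid oxidation, with the block without rounding variance, which also called adipocyte markers.

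**Figure D2:**
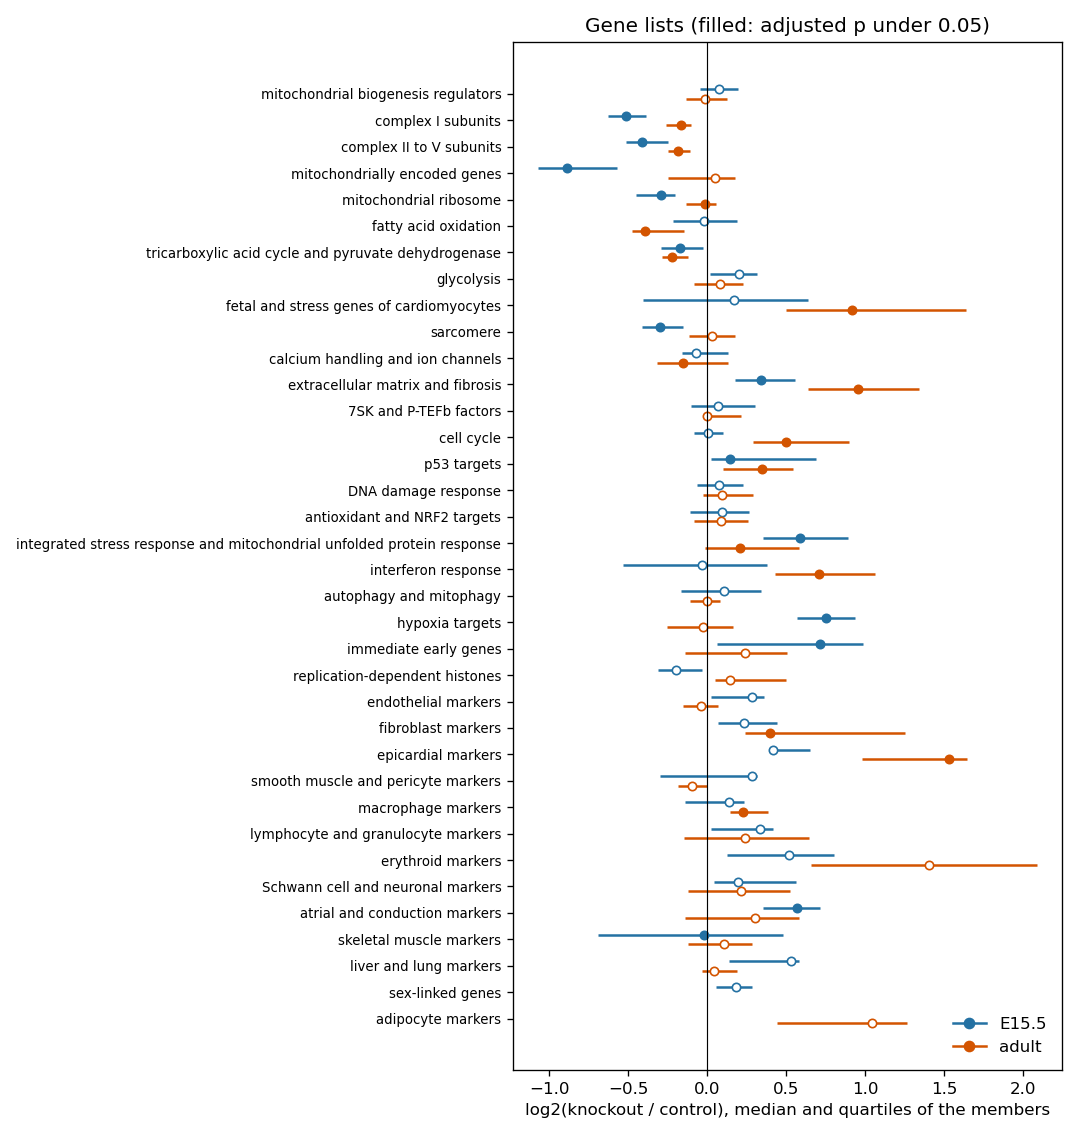
Median log2 change of each gene list (points) with the quartiles of its members (lines), at E15.5 and in the adult; filled points are lists with a camera adjusted p under 0.05. The complex I median was -0.52 at E15.5 and -0.17 in the adult, and the matrix median was 0.34 and 0.95.

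Among 9768 genes tested in both models, 7 were called in both in the same direction, all 7 higher, where independent lists of these sizes would share 1.46 (one-sided Fisher's exact test over genes, which are not independent replicates, p = 0.000578). They were Gria3, Thbs1, Btg2, Sema3b, Serpinf1, Lad1 and Mthfd2. Without number 1 of the knockout, Lad1, Thbs1 and Btg2 lost their E15.5 calls (adjusted p = 0.0843, 0.168 and 0.195, limma), and the others kept theirs. The adult calls that enter this overlap are loose, since 53.5% of adult calls were false in the simulation. Gria3, a glutamate receptor subunit, was 28.3 ± 1.15 against 57.3 ± 0.58 at E15.5 (SD, n = 3) and 1 ± 0.00 against 6 ± 0.00 in the adult (SD, n = 2). Thbs1, the matrix protein thrombospondin 1, was 59.7 ± 3.21 against 94.7 ± 3.06 at E15.5 and 12 ± 5.66 against 28 ± 5.66 in the adult. Kcnj3 was called in both in opposite directions. The overlap ranged from 0 (block without rounding variance, limma, with 1422 E15.5 and 1824 adult genes at an unadjusted p under 0.05) to 81 (neither) over the settings run. The models differ in age, tissue part and kind of deletion, and a test of the difference between them was not run.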

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

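No test was run in this part. Ckm, muscle creatine kinase, fell by 1 on the log2 scale at E15.5, with all 3 knockout values below the wild type, and had a change of 0.21 in the adult, with both knockout values above the controls, which was not called. Kcnj3, an atrial potassium channel subunit, rose by 0.76 at E15.5 and changed by -0.76 in the adult. Hist1h1c, a linker histone, had -0.25 at E15.5 and 0.2 in the adult and was called in neither. These genes stood out because every knockout sample lay on 1 side of its controls in the embryo and on the other side in the adult. The difference between the models was not tested.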

How the results depend on the processing

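The leave-outs, scaling, filter, pseudocounts and block were planned; the rounding variance, the priors from variance percentiles, the mean of at least 10, the crossed block and the removal of genes with changed signs were chosen after seeing the data, as was the reported fit itself, which adds rounding variance to the replicate block. Counts are higher then lower genes (limma, adjusted p under 0.05 unless stated), against 72 and 14 at E15.5 and 347 and 141 in the adult. The planned fit, with no replicate block and no rounding variance, called 701 and 339 at E15.5 and 1133 and 489 in the adult. The replicate block without rounding variance called 0 and 0 (1422 at an unadjusted p under 0.05) and 833 and 297. These larger adult sets do not contain the reported one: of its 488 calls, the planned fit called 85 and the block without rounding variance 23. Rounding variance with no block called 430 and 174, and 252 and 157. The more cautious priors called 0 and 0 at E15.5 (75th percentile, 1642 at an unadjusted p under 0.05, and 90th, 1591), and in the adult 73 and 35 (75th) and 0 and 0 (90th, 1724 at an unadjusted p under 0.05). At E15.5 median-of-ratios scaling called 26 and 13, no filter 480 and 121, a pseudocount of 0.1 7 and 1, of 5 195 and 37, and a mean of at least 10 0 and 0 (1100 at an unadjusted p under 0.05). An adjusted p under 0.01 left 11 and 4, and 204 and 77. A log2 change of at least 1 left 37 and 2, and 109 and 28. Leaving out 1 sample called 171 to 422 and 40 to 87 at E15.5, where the block also takes its same-numbered partner out of the comparison. In the adult it called 391 to 983 and 227 to 305; the block leaves no residual degrees of freedom there, so it was left out and the lone sample was assumed to vary like the other group. The crossed replicate block called 4361 and 1924 in the adult, which is void since the fixed totals leave only rounding as residual. Apart from the crossed block, the cause of these differences was not tested.

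Larp7 at E15.5 kept its log2 change of -1.04 but lost its call with the block without rounding variance (adjusted p = 0.473, limma), the 75th (0.385) and 90th percentile priors (0.407) and a mean of at least 10 (0.332). In the adult it was called in no setting run. Of 35 lists, camera called 13 at E15.5 and 15 in the adult, 9 and 10 of these also with an estimated correlation, which rests on 1 residual degree of freedom in the adult. The directional test of fry called 0 in both (8 and 11 at an unadjusted p under 0.05). In the adult the planned fit called 1 list, adipocyte markers, which is not among the 15, so that 0 of the 15 held under it. The block without rounding variance called 3, of which complex I and fatty acid oxidation are among the 15. Genes called in both models in the same direction numbered 7, and 81 with the planned fit, 0 with the block without rounding variance, 20 with rounding variance and no block, 2 with scaling, 27 with no filter, 1 and 11 with pseudocounts of 0.1 and 5, 0 and 0 with the priors, 0 with a mean of at least 10, and 6 to 33 without 1 sample (limma). Of 1449 values of named genes at E15.5 under other settings 325 kept a call, 230 lost it, 861 stayed without a call, 33 gained one and 0 reversed, and of 1670 in the adult 734, 351, 544, 41 and 0. Count-based tools, voom, a sex covariate and the test between models were not run.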

Other observations

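The tests of the fixed totals, of changed signs and of the fibroblast markers were chosen only after the results were seen. In the adult, glucose genes went both ways within a list that was not called (camera, adjusted p = 0.649). Slc2a4, the insulin-responsive glucose transporter, fell from 406 ± 11.3 to 258 ± 11.3 (SD, n = 2), Pfkfb1 fell from 11 ± 1.41 to 5 ± 1.41, and Pfkp rose from 46 ± 19.8 to 83.5 ± 19.1. Pink1, a kinase of mitophagy, fell from 652.5 ± 16.3 to 479 ± 15.6. Adipocyte markers had 7 of 8 positive changes and were not called (camera, adjusted p = 0.129), but were called as higher with no replicate block and no rounding variance (adjusted p = 0.0376) and with the replicate block without rounding variance (adjusted p = 0.0025), and in no other setting run, with medians between -0.05 and 2.67. Erythroid markers in the adult had 8 of 8 positive changes with a median of 1.40 and were not called (camera, adjusted p = 0.151), but were called with the 75th and 90th percentile priors (adjusted p = 0.00723 with the latter) and without either number 1 sample, with medians between 0.37 and 2.30. The globin genes varied between samples of a group: Hbb.bs was 718 and 61 in the adult controls and 613 and 1392 in the knockout, with a control value that meets the fixed total only with a changed sign. Xist rose in the adult (112 ± 26.9 against 154 ± 26.9, adjusted p = 0.0471, limma), and was present in all 4 adult samples.

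The fixed totals may come from an adjustment by replicate number before deposit, such as removal of a number effect. The same-number pairing gave fixed totals in 99.55% of E15.5 genes with a mean of at least 10, and no other pairing in either model in more than 28.56%. A candidate explanation of the exceptions is that values driven below 0 were then made positive: 1 changed sign restored the total in 99.4% of them, against 2.01% under a wrong pairing. Which step did this is not given in the sources used here, and no biological explanation was tested.

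The rise of matrix and fibroblast genes in the adult could reflect a lower share of cardiomyocyte RNA in the knockout samples, which would raise endothelial and mural markers by about as much. The endothelial median lay 0.435 below the fibroblast median and 0.993 below the matrix median on the log2 scale, more than the interquartile range of 0.226 among endothelial markers. Smooth muscle and pericyte markers lay 0.493 and 1.05 below, with an interquartile range of 0.186. Since the matrix and fibroblast lists share members, their differences are not independent. The fibroblast markers themselves spread over 1.011, a wider bound used at first that the fibroblast difference did not exceed. Since the narrower bound was chosen after these values were seen, it cannot decide the question. The values show only that the endothelial and mural medians (-0.04 and -0.10) did not rise along with the matrix and fibroblast medians. A lower cardiomyocyte share stays open, as do more fibroblasts or changed expression within cells, which were not tested.

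Genes near Larp7 might differ at E15.5 through a local effect of the targeted allele or DNA carried along with it. Of 46 tested genes within 5 Mb, 0 were called in limma and 10 had an unadjusted p under 0.05 (21.7%, against 13.9% elsewhere). At the called share of 0.632% elsewhere, 0.29 calls would fall in the window, so that the bound set beforehand, at most 1 call, could not tell the cases apart, and the question stays open.

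The 10 ways to split the E15.5 samples are too few for a share under 0.05. The real split called 72 higher and 14 lower genes and 13 lists. The highest other split called 78 genes in a direction and 18 lists. Since the direction of another split is arbitrary, its larger direction was compared: counting the real split, 3 of the 10 splits had at least the real number of higher calls there, 5 at least the real number of lower calls, and 3 as many lists. These other splits leave a same-numbered pair together in each group, unlike the real one. The 3 others that part every pair called 0 genes each in limma, and 11, 6 and 12 lists, of which 0, 1 and 0 with an estimated correlation against 9 for the real split. The complex I median was -0.52 in the real split and -0.07, -0.06 and 0.32 in these 3, whose sign has no meaning. In the other 6 splits, where a single pair is parted, its size was that of the genotype difference within that pair: -0.32, -0.64 and -0.41 for numbers 1, 2 and 3.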
